A study of Mus musculus with 22 samples.

How the data were processed

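Poly(A) RNA from liver nuclei of CD-1 (ICR) mice was sequenced in 22 libraries that fall into 10 groups. Male and female mice received TCPOBOP at 3 mg/kg or vehicle (DMSO in corn oil) and were studied after 3 h and 27 h, with 2 pools per group. Male mice received PCN at 50 mg/kg or vehicle and were studied after 3 h, with 3 pools per group. Each pool joined nuclear RNA from 4 livers at 3 h and from 3 livers at 27 h. Per the labels, the TCPOBOP libraries were stranded and the PCN libraries unstranded. The labels name a directional kit for every library, which is at odds with the second label and stays open.

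Per the submitters' processing notes, the authors mapped reads to mouse genome build mm9 with TopHat2, counted them with HTSeq 0.6.1p1 or featureCounts 1.4.6-p5 and compared groups with edgeR. The legend of the authors' deposited table names gene-body counting for every comparison, edgeR for the 4 TCPOBOP comparisons and HTSeq for the PCN comparison. Which counter made which library, and which genes the authors filtered out, is not stated there. The authors' deposited table has 24197 RefSeq genes, and for each of 5 comparisons it lists a ratio of treated over vehicle, a signed fold change, the mean FPKM of the vehicle and of the treated pools and an adjusted p-value. FPKM, as the authors deposited it, is the number of fragments scaled to gene length in kilobases and to the mapped fragments of the library. The table has no value per library, so no SD, standard error or test across pools was computed, and each FPKM printed is the authors' mean of a group's pools.

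The plan, fixed before the data were examined, was to fit counts or normalized values per library where they were held, and otherwise to describe the authors' ratios and adjusted p-values at 0.05. The second course was followed. A gene was called raised or lowered where the authors' adjusted p was below 0.05, and the sign came from the authors' ratio. Tests of sex, time and compound differences need values per library and were not run. Genes called in opposite directions were listed instead, with the larger of the 2 adjusted p-values beside each. That value belongs to a call against vehicle and does not bound the error of a difference. The adjustment covers all genes of a comparison and not those picked for opposite directions, among which false calls may be more frequent. The count of calls adjusted over the list alone was not computed because the table gives adjusted p-values only.

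Depth was estimated from the table. In 3335 genes with 1 location and a span below 1500 bp, low FPKM values multiplied by the span and the number of pools fell on a few fixed steps, each the worth of 1 read in 1 pool. Between 89.8% and 95.3% of these low values per group lay within 0.1% of a whole number of reads. The steps gave about 25400000 to 46700000 mapped fragments per pool in the TCPOBOP set and 19000000 to 31900000 in the PCN set, so that 1 read in a gene of 1 kb was worth 0.0214 to 0.0394 FPKM and 0.0314 to 0.0525 FPKM. The procedure was tested on simulated data and recovered the simulated depths. The length behind the FPKM of longer genes did not follow from their span and is not given.

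Expressed genes were those with a mean of at least 1 FPKM in either group of a comparison. A gene below that level in vehicle thus enters only through a higher treated mean, which favours rises in lists of such genes. Before the data were examined, 32 gene lists with 596 symbols were fixed, of which 593 symbols matched the table, some through synonyms. For lists with at least 5 expressed members, a 2-sided Fisher's exact test compared the share of called members with that among other expressed genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The test does not look at direction. The median log2 ratio of a list was set against 10000 random lists matched on mean expression in 20 bins. Both steps were tested on simulated lists. Genes within a list and genes near each other are not independent, so these p-values describe gene counts and not animals.

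Levels in vehicle groups were compared as log2 quotients of mean FPKM with 0.1 added to each, less the median log2 quotient of expressed genes. For female over male vehicle that median was -0.034 at 3 h and 0.059 at 27 h. The check against the vehicle group of the other time and the clock phase were centred likewise. A gene was called sex-biased where the centred quotient of female over male vehicle was at least 2-fold in either direction, with no test. Overlaps between comparisons were counted among genes expressed in both, with the number expected from independent lists and Fisher's exact test. For calls in opposite directions no expected number was computed.

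The genes named were drawn from a set fixed by rule before the data were examined. It holds the 8 called genes with the largest rise and the 8 with the largest fall per comparison at 1 FPKM or more, up to 3 called members of each list with the smallest adjusted p, 14 genes fixed in advance, and the 5 with the largest sex bias in each direction. Genes called in opposite directions in the 2 sexes or at the 2 times, and further list members named as examples or to complete a count, were added after their values were seen, and not every gene of the set is printed. Sex bias was ranked by the smaller of the log2 quotients at 3 h and 27 h.

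Alternatives were a stricter adjusted p of 0.01, a minimum of 2-fold, a minimum of 1 FPKM, and sex bias from the vehicle groups of the other time. Further alternatives, chosen after seeing the data, were the vehicle group of the same sex at the other time (set against expressed genes that were not called), the sign from the quotient of mean FPKM, a background of 0.1 FPKM for the lists, and sex bias at both times. Families of genes that share a symbol stem, clock phase, transcripts of the respiratory chain and neighbours of strongly raised genes were tested for the closing section. The neighbours were the nearest expressed genes within 50 kb of a gene raised at least 4-fold, with and without other such genes, and without genes of the same symbol stem, with strands taken by symbol from a reference annotation. Positions are 1-based mm9 coordinates from the table. No genome sequence of that build was used here. Computation used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.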

Results

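Nuclear poly(A) RNA of mouse liver was measured after TCPOBOP, an agonist of the nuclear receptor CAR (Nr1i3), and after PCN, an agonist of the nuclear receptor PXR (Nr1i2). The 22 libraries form 10 groups and 5 comparisons, each with its own vehicle pools. TCPOBOP at 3 mg/kg was studied in males and females after 3 h and 27 h, with 2 pools per group from 8 mice at 3 h and 6 mice at 27 h. PCN at 50 mg/kg was studied in males after 3 h, with 3 pools per group from 12 mice. The labels give the same late-morning collection window on both days. The depth, estimated from the table, was about 25400000 to 46700000 fragments per pool in the TCPOBOP set and 19000000 to 31900000 in the PCN set. All levels, ratios and adjusted p-values of genes are from the authors' deposited table, where a group is a single mean with no spread between pools. The number of expressed genes, at 1 FPKM or more in either group, ran from 8918 in the PCN comparison to 10480 in males at 27 h.

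TCPOBOP raised 148 genes and lowered 62 in male liver at 3 h by the authors' deposited table, and raised 304 and lowered 203 in female liver at that time. After 27 h the same table called 1162 genes raised and 884 lowered in males and 844 raised and 692 lowered in females. PCN raised 1264 genes and lowered 1102 in male liver at 3 h. Against the vehicle pools of the same sex at the other time, 960 of the 1536 female 27 h calls (62.5%) had the same direction, the lowest share of the TCPOBOP comparisons in that check. Both quotients of this check share the treated pools, so some agreement arises without a change. Among expressed genes that were not called, 57.7% agreed in 3 h males, 68.2% in 3 h females, 61.1% in 27 h males and 44.2% in 27 h females, against 90.8%, 88.4%, 84.7% and 60.4% of expressed genes that were called. The female vehicle pools of the 2 times differed by at least 2-fold in 1445 genes, against 284 genes between the male vehicle pools. Numbers of calls were not compared between comparisons, since pools and depth differed.

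**Figure D1:**
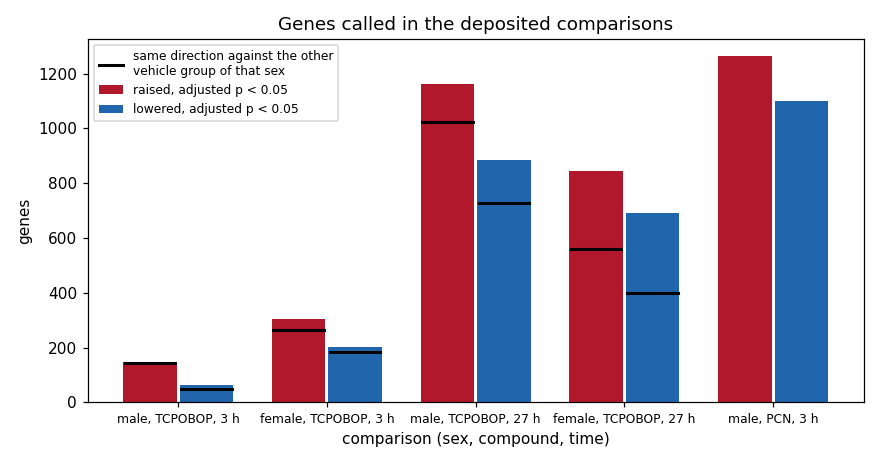
Genes called raised (red) or lowered (blue) at adjusted p below 0.05 in the authors' deposited table, by comparison. Black lines mark the calls with the same direction against the vehicle group of the same sex at the other time, which number 960 of 1536 in females at 27 h. The PCN comparison has no such second vehicle group.

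The first question was which genes respond to TCPOBOP in male liver within 3 h. The strongest rises included several genes of drug-metabolising enzyme families. Cyp2b10, the cytochrome P450 gene best known as a CAR target (NM_009999, chromosome 7, 26682677 to 26711643), rose 112-fold from 0.755 to 84.9 FPKM with adjusted p = 8.20e-190 in the authors' deposited table. Cyp2c55 (NM_028089, chromosome 19, 39081509 to 39117177) rose 82.2-fold and Cyp3a11 (NM_007818, chromosome 5, 146666183 to 146691430) rose 3.78-fold in the authors' deposited table. Gadd45b, a stress-responsive gene (NM_008655, chromosome 10, 80392836 to 80394949), rose 11.6-fold to 10.1 FPKM by the authors' deposited table. Others among the 8 largest rises, which did not include Cyp3a11, were Cyp2c53-ps (30.1-fold), Slc15a2 (log2 ratio 4.46), Ces2a (9.74-fold), Gstt3 (8.96-fold) and Lect1 (8.14-fold), as the authors' deposited table lists them. Reads shared between close paralogs of the Cyp2b, Cyp2c and Cyp3a families cannot be separated in this table.

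Of the 20 expressed members of the PXR list, 16 rose in 3 h males and none fell (adjusted p = 1.08e-23, Fisher's exact test), and 11 of 19 members of the CAR list rose with none falling (adjusted p = 5.52e-14). The lists overlap in genes such as Cyp2b10, Por and Ces2a. Por, which passes electrons to microsomal P450 enzymes, rose 5.69-fold, and Alas1, the first enzyme of heme synthesis, rose 2.54-fold by the authors' deposited table. Conjugating enzymes followed, with 8 of 26 raised (adjusted p = 1.23e-07), among them Gstm3 (5.99-fold) and Ugt1a1 (2.16-fold) in the authors' deposited table. Transporters had 3 calls among 18 (adjusted p = 0.0166). Slco1a4 rose 1.80-fold and Abcc2 rose 1.64-fold, while the citrate transporter Slc13a5 fell 1.84-fold by the authors' deposited table. The list of p53 and growth arrest genes had 4 calls among 13 (adjusted p = 0.000396), with Gadd45a and Gadd45b raised and Gadd45g and Btg2 lowered. Pericentral genes had 4 calls among 13 (adjusted p = 0.000396), and the raised ones, Cyp2c29, Cyp1a2 and Lect2, include P450 genes that are also drug-responsive. The fourth, Slc1a2, fell.

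The largest falls in 3 h males were Trpv1 (5.43-fold), the fasting hormone gene Fgf21 (3.77-fold), the acute-phase gene Saa3 (3.27-fold), Cyp2c69 (3.22-fold) and Nnmt (2.87-fold) in the authors' deposited table. Ppp1r14a (2.64-fold) and Serpina7 (2.46-fold) completed the 8 with Prss22, which the authors' deposited table lists at 1.80 FPKM in vehicle and at 0 after TCPOBOP. Female-biased genes passed the list test on 3 calls among 9 (adjusted p = 0.00226). Of these, Cyp2c40 fell 2.38-fold and Cyp2c69 fell 3.22-fold, while Cyp3a44 rose 5.55-fold from 0.283 FPKM, in the authors' deposited table. No other list passed. Immediate early genes had a median log2 ratio of -0.41 and acute-phase genes of -0.53, each below all of the matched random lists, with 1 call among 16 (Fos) and 2 calls among 20 (Saa3 and Socs3). Of the genes named here, Prss22, Socs3, Fos and Btg2 did not hold their direction against the male 27 h vehicle pools.

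The same question was asked in female liver at 3 h. Cyp2c55 rose 214-fold, Cyp2b10 rose 127-fold to 119 FPKM and Cyp3a11 rose 5.56-fold by the authors' deposited table. The rest of the 8 largest rises were Cyp2c53-ps (80.0-fold), Ces2a (32.2-fold), Akr1b7 (29.1-fold), Cyp2c29 (15.4-fold), Gadd45b (14.8-fold) and Tsku (11.2-fold) in the authors' deposited table. The PXR list had 18 of 22 members raised (adjusted p = 7.65e-20), and the CAR list had 16 of 22 raised and 1, Cyp2c38, lowered (adjusted p = 3.04e-18), a fall not kept against the female 27 h vehicle pools. The CAR-list rises of Cyp2a5, Cyp1a2 and Ephx1 were not kept against these pools either. Neither were the PXR-list calls of Papss2, Cyp3a59, Slco1a4 and Cyp3a25. The female vehicle pools of 3 h and 27 h were at least 2-fold apart in 1445 genes. This check thus cannot tell a false call from a change between the vehicle pools. Por rose 5.68-fold and Alas1 rose 6.55-fold by the authors' deposited table. Conjugating enzymes had 11 of 27 raised (adjusted p = 9.08e-08), with Gstt3 at 7.66-fold, Sult2a1 at 3.74-fold and Gstt1 at 3.37-fold in the authors' deposited table. Transporters were split, with 3 raised and 3 lowered among 18 (adjusted p = 0.000551). Abcc3 rose 2.91-fold and the phospholipid transporter Abcb4 fell 1.83-fold by the authors' deposited table.

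Proliferation genes were called in females already at 3 h, with 4 of 9 expressed members raised (adjusted p = 0.00138). Cyclin D1 (Ccnd1) rose 3.06-fold, the proliferation marker Mki67 rose 3.03-fold and Cdc20 rose 3.03-fold by the authors' deposited table, and Myc was the other. Kupffer cell markers had a median log2 ratio of 0.42 in the same comparison. In 3 h males Ccnd1 stood at 1.53-fold with adjusted p = 0.0644 and Mki67 fell short of a call at log2 -0.24 in the authors' deposited table, and the sex difference was not tested. The growth arrest list had 4 raised and 1 lowered among 13 (adjusted p = 0.000719), with Gdf15 up 7.26-fold and Gadd45a up 2.54-fold in the authors' deposited table. Genes of fatty acid oxidation had 4 lowered and 1 raised among 23 (adjusted p = 0.00755). The receptor gene Ppara fell 1.84-fold, the lipid droplet gene Plin2 fell 1.97-fold and Fgf21 fell 4.23-fold by the authors' deposited table, and Cpt1a fell and Vnn1 rose. Plin2 did not hold its direction against the female 27 h vehicle pools. Male-biased genes had 6 lowered and 3 raised among 19 (adjusted p = 3.18e-07), with Nudt7 down 2.62-fold and Cyp2u1 down 3.19-fold in the authors' deposited table. Female-biased genes had 7 raised and none lowered among 27 (adjusted p = 0.000707), with Sult2a1, Sult2a2 (2.29-fold) and Cyp3a44 (2.26-fold) in the authors' deposited table.

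Further lists that passed in 3 h females were NRF2 targets (2 raised and 1 lowered of 10, adjusted p = 0.0192), clock genes (3 raised and 2 lowered of 17, adjusted p = 0.00208), liver transcription factors (2 raised and 3 lowered of 23, adjusted p = 0.00755) and pericentral genes (2 raised and 3 lowered of 14, adjusted p = 0.000943). Gstm3 rose 5.21-fold, the receptor gene Ahr rose 2.10-fold and Gclc fell 1.99-fold by the authors' deposited table. Among clock genes Bhlhe40, Per3 and Dbp rose, and Arntl was among those that fell. Dbp and Per3 did not hold their rise against the female 27 h vehicle pools, and Bhlhe40 did. Large falls included Trpv1 (4.93-fold), BC021614 (4.83-fold), Fgf21, G0s2 (3.90-fold), Xlr3a (3.48-fold), Cyp2u1 and Ppp1r3c (3.01-fold) in the authors' deposited table.

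**Figure D2:**
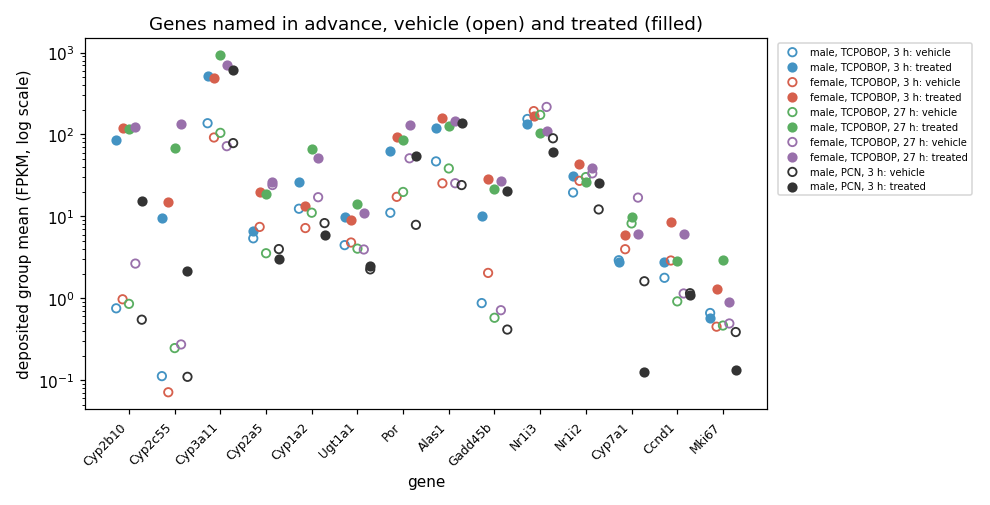
Mean FPKM (log axis) of the 14 genes fixed in advance, in vehicle pools (open circles) and treated pools (filled circles) of the 5 comparisons, from the authors' deposited table. Cyp2b10 lay between 0.548 and 2.66 FPKM in the vehicle groups and between 15.3 and 124 FPKM in the treated groups, with PCN lowest. No error bars are drawn because the table has group means only.

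At 27 h in males, the drug-metabolism response was joined by cell-cycle genes. Cyp2c55 rose 283-fold to 68.5 FPKM, Cyp2b10 rose 138-fold to 118 FPKM and Cyp3a11 rose 9.34-fold to 941 FPKM by the authors' deposited table. Of 27 expressed cell-cycle genes, 23 rose and 1, Mcm10, fell (adjusted p = 5.75e-15), with a median log2 ratio of 1.24. Markers of Kupffer cells, stellate cells and sinusoidal endothelium stood at medians of 0.28, 0.34 and 0.26 in the same comparison. A cell-cycle gene below 1 FPKM in vehicle was counted only where the treated mean reached that level. This filter favours rises in the share and the median, here as in females. The mitotic gene Cdc20 rose by a log2 ratio of 4.32, Mki67 rose 6.63-fold and Top2a rose 4.94-fold by the authors' deposited table. Among the 20 CAR-list members 16 rose and 2, Cyp2c38 and Cyp2c39, fell (adjusted p = 1.24e-11), neither fall being kept against the male 3 h vehicle pools. Among the 19 PXR-list members 17 rose (adjusted p = 4.62e-11). Conjugating enzymes had 17 raised and 1 lowered among 26 (adjusted p = 1.89e-08), with Gstm3 at 25.3-fold and Gstt3 at 12.8-fold in the authors' deposited table.

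Cholesterol synthesis genes had 8 raised and none lowered among 19 in 27 h males (adjusted p = 0.0133). Sc5d rose 2.25-fold and Idi1 rose 2.20-fold by the authors' deposited table. Glucose-handling genes had 5 lowered and 2 raised among 14 (adjusted p = 0.00749). Igfbp1 fell 2.99-fold and the gluconeogenic enzyme Fbp1 fell 1.68-fold, while the glycogen phosphorylase Pygl rose 1.89-fold by the authors' deposited table. Acute-phase genes had 9 lowered and 2 raised among 20 (adjusted p = 0.000351). The chemokine Cxcl1 fell 3.41-fold and Socs3 fell 2.31-fold, while Orm3 rose 3.53-fold by the authors' deposited table. Immediate early and stress genes had 6 lowered and 4 raised among 14 (adjusted p = 4.04e-05). The metallothioneins Mt1 and Mt2 fell 6.45-fold and 6.03-fold and Junb fell 2.71-fold, while Fosl2 rose 2.83-fold by the authors' deposited table.

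Transporters in 27 h males had 4 raised and 6 lowered among 18 (adjusted p = 0.000585). The sterol transporter Abcg5 fell 2.73-fold and Slc13a5 fell 3.71-fold, while Abcc2 rose 2.67-fold by the authors' deposited table. NRF2 targets had 5 raised and 2 lowered among 10 (adjusted p = 0.000747), the raised ones being Gstm3, Ephx1, Srxn1, Gsta4 and Ces2g. Genes of the unfolded protein response had 6 raised and 2 lowered among 14 (adjusted p = 0.00171), and 3 of the 6 held against the male 3 h vehicle pools. Periportal genes had 5 lowered and 1, Cdh1, raised among 14 (adjusted p = 0.0312), with Etnppl down 2.61-fold and Pck1, the gluconeogenic gatekeeper, down 2.06-fold in the authors' deposited table. Pericentral genes had 3 raised and 4 lowered among 13 (adjusted p = 0.00508). Growth arrest genes had 3 raised and 4 lowered among 14 (adjusted p = 0.00749), with Gadd45b up 38.5-fold and Gadd45a up 5.14-fold in the authors' deposited table. Clock genes had 3 raised and 5 lowered among 16 (adjusted p = 0.00489), with Nfil3 down 2.16-fold, Dbp up 2.29-fold and Per3 up 1.96-fold in the authors' deposited table.

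Male-biased genes had 10 raised and 3 lowered among 23 in 27 h males (adjusted p = 6.13e-05), with Elovl3 up 3.11-fold and Ugt2b1 up 2.79-fold in the authors' deposited table. Against the male 3 h vehicle pools 3 of the 10 kept their direction, and Elovl3 did not. Female-biased genes had 2 raised and 3 lowered among 11 (adjusted p = 0.0383). Hao2 rose 4.51-fold and Cyp4a10 fell 4.75-fold by the authors' deposited table, and the other calls were Slc22a26, Cyp2c40 and Cyp2c69. Other large rises included Cyp2c53-ps (254-fold), Krt4 (122-fold) and Akr1b7 (29.9-fold), and the largest falls were Rubie (7.36-fold), Mt1, Mt2, Dio3os (5.91-fold), Cxcl14 (5.59-fold), Rdh9 (5.17-fold), Cyp46a1 (5.02-fold) and Cyp4a10 in the authors' deposited table. Krt4 started from 0.0115 FPKM in the authors' deposited table, below the worth of 1 read in a gene of 1 kb. The receptor gene Nr1i3 itself fell 1.60-fold and Nr1i2 stood at log2 -0.13 with adjusted p = 0.985 in the authors' deposited table.

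At 27 h in females, Cyp2c55 rose 502-fold to 132 FPKM, Cyp2b10 rose 49.1-fold to 124 FPKM and Cyp3a11 rose 10.2-fold to 706 FPKM by the authors' deposited table. Cyp2c53-ps (1919.6-fold, from 0.029 FPKM), Krt4 (128-fold, from 0.0174 FPKM), Gadd45b (39.4-fold), Akr1b7 (29.8-fold) and Gstm3 (29.2-fold) were the other large rises in the authors' deposited table. Mir365-2 belonged to the same 8 and was listed at 0 in vehicle and at 2.12 FPKM after TCPOBOP in the authors' deposited table. FPKM is scaled to gene length, so in a short gene such a value can rest on few reads. The PXR list had 16 raised and 1, Cyp3a16, lowered among 22 (adjusted p = 3.15e-10), the CAR list 13 raised and 1, Cyp2a4, lowered among 22 (adjusted p = 6.17e-07), and conjugating enzymes 15 raised among 27 (adjusted p = 1.72e-06). Cell-cycle genes had 9 raised and 2 lowered among 19 (adjusted p = 2.31e-05). Ccnd1 rose 5.53-fold, the replication gene Mcm4 rose 3.45-fold and Mcm10 fell 2.37-fold by the authors' deposited table. The other fall was in Tk1, and neither fall was kept against the female 3 h vehicle pools, while all 9 rises were. Mki67 stood at 1.89-fold with adjusted p = 0.125 by the authors' deposited table.

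Glucose-handling genes had 8 lowered and 1, Pygl, raised among 14 in 27 h females (adjusted p = 4.05e-05). The glucose transporter Slc2a2 fell 3.00-fold, Igfbp1 fell 3.02-fold and Pygl rose 2.15-fold by the authors' deposited table. Against the female 3 h vehicle pools 5 of the 8 kept their direction. Periportal genes had 6 lowered and 1, Cdh1, raised among 14 (adjusted p = 0.00222), and 2 of the 6 kept their direction against the same pools. Etnppl fell 5.40-fold and Gls2 fell 2.15-fold by the authors' deposited table, and neither fall was kept. Clock genes had 8 lowered and 2 raised among 17 (adjusted p = 4.05e-05). Dbp (NM_016974, chromosome 7, 52960617 to 52965573) fell 4.08-fold, Per1 fell 3.21-fold and Per3 fell 2.32-fold by the authors' deposited table. Of the 8, 3 kept their direction against the female 3 h vehicle pools, where Dbp stood at 0.966 FPKM in the authors' deposited table, against 40.6 FPKM in the female 27 h vehicle pools. Genes of the unfolded protein response had 5 raised and 2 lowered among 14 (adjusted p = 0.00222), with 2 of the 5 raised kept. The raised were Hspa5, Dnajb9, Sdf2l1, Hyou1 and Pdia4, and the lowered Chac1 and Derl3.

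Immediate early and stress genes had 6 lowered and 4 raised among 15 in 27 h females (adjusted p = 1.56e-05). Mt1 fell 7.58-fold and Junb fell 3.79-fold, while Fosl2 rose 5.93-fold by the authors' deposited table. Transporters had 7 lowered and 4 raised among 19 (adjusted p = 2.31e-05), with Abcc4 up 3.94-fold and Abcc2 up 2.88-fold in the authors' deposited table. NRF2 targets had 5 raised among 12 (adjusted p = 0.0274), which were Gstm3, Abcc4, Srxn1, Ces2g and Ephx1. Pericentral genes had 3 raised and 5 lowered among 14 (adjusted p = 0.000336). Cyp2c29 rose 23.3-fold, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 2.71-fold by the authors' deposited table, a fall not kept against the female 3 h vehicle pools. Male-biased genes had 7 raised and none lowered among 20 (adjusted p = 0.0229), with Elovl3 up 13.9-fold and Ugt2b1 up 3.61-fold in the authors' deposited table. Female-biased genes had 8 lowered and 4 raised among 27 (adjusted p = 0.000188). Cyp3a16 fell 7.58-fold and Cux2, a repressor of male-biased genes, fell 10.8-fold by the authors' deposited table. The other largest falls were Dnaic1 (15.5-fold), Dio3os (10.1-fold), Bmf (9.76-fold), Rubie (9.56-fold), Cyp26b1 (9.26-fold), Lgi4 (8.36-fold) and Chac1 (8.15-fold) in the authors' deposited table.

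PCN was studied in males at 3 h to find the early genes of PXR activation. Gadd45b rose 54.1-fold from 0.416 to 20.4 FPKM, Cyp2b10 rose 31.1-fold to 15.3 FPKM and Cyp3a11 rose 8.82-fold to 615 FPKM with adjusted p = 7.51e-118 in the authors' deposited table. The other large rises were Akr1b7 (44.0-fold), Mir6392 (27.5-fold), Cyp2c55 (21.7-fold), Gstm3 (20.8-fold), Ces2a (20.5-fold) and Nnmt (13.7-fold) in the authors' deposited table. Of 19 PXR-list members 15 rose and none fell (adjusted p = 2.30e-06), while the CAR list had 7 raised and 4 lowered among 19 (adjusted p = 0.00288) with a median log2 ratio of -0.07. Cyp2b9, Cyp2c38, Cyp2c39 and Aldh3a2 were the 4. Of the CAR list, Cyp2b10, Cyp2c29, Cyp2c55, Por, Aldh1a7 and Ces2a rose with PCN and are also on the PXR list. The results of these lists are therefore not independent. Nr1i2, the gene of PXR, rose 2.34-fold and Nr1i3 fell 1.32-fold by the authors' deposited table. Alas1 rose 6.51-fold and the bile salt and drug uptake transporter Slco1a4 rose 9.09-fold by the authors' deposited table. Conjugating enzymes had 7 raised and 5 lowered among 24 (adjusted p = 0.00733).

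Cholesterol synthesis genes had 14 lowered and none raised among 19 with PCN (adjusted p = 1.86e-05), with a median log2 ratio of -0.68. Sc5d fell 3.26-fold, the sterol sensor partner Insig1 fell 3.23-fold and Fdft1 fell 2.08-fold by the authors' deposited table. Acute-phase genes had 15 raised and 1, Ccl2, lowered among 20 (adjusted p = 1.91e-06). Cebpd rose 3.08-fold, Crp rose 2.70-fold and haptoglobin (Hp) rose 2.13-fold by the authors' deposited table. Growth arrest genes had 7 raised and 2 lowered among 12 (adjusted p = 0.000851), with Gadd45a at 4.11-fold and Gadd45g at 2.52-fold in the authors' deposited table. Clock genes had 8 lowered and 1, Bhlhe40, raised among 15 (adjusted p = 0.00555). Dbp fell 5.99-fold, Per3 fell 2.96-fold and Per2 fell 2.41-fold by the authors' deposited table. Lipogenic genes had 4 raised and 5 lowered among 17 (adjusted p = 0.0142). Pnpla3 rose 6.62-fold and Thrsp rose 4.05-fold, while Srebf1 fell 1.90-fold by the authors' deposited table. The bile acid gene Cyp7a1 fell 10.8-fold from 1.62 to 0.128 FPKM by the authors' deposited table, though its list did not pass (adjusted p = 0.165).

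Male-biased genes had 10 lowered and 3 raised among 22 with PCN (adjusted p = 0.000966), with Cyp2u1 down 4.26-fold and Hsd3b5 at log2 -1.32 in the authors' deposited table. Female-biased genes had 6 lowered and none raised among the 7 expressed in males (adjusted p = 0.00277), with Cyp2c69 down 10.9-fold and Cyp2c40 down 7.07-fold in the authors' deposited table. Cyp3a44, a list member below the minimum of 1 FPKM and so not counted, was called raised with PCN. Genes of fatty acid oxidation had 7 lowered and 2 raised among 19 (adjusted p = 0.0474), with Fgf21 down 7.86-fold and Angptl4 up 2.04-fold in the authors' deposited table. Pericentral genes had 2 raised and 4 lowered among 11 (adjusted p = 0.0463). Ribosomal protein genes, a list fixed as a sign of cytoplasmic RNA in the nuclei, had 17 of 23 raised and none lowered (adjusted p = 2.30e-06). Their median log2 ratio was 0.41, and Rpl3 rose 1.61-fold by the authors' deposited table. The same list had 0, 0, 2 and 1 calls in the TCPOBOP comparisons in the order given above, with medians of -0.03, 0.29, 0.24 and 0.22, the last 3 above 99% of random lists as well. Ratios in the PCN columns stood above the quotients of mean FPKM by a median log2 of 0.17, against -0.01 to 0.06 in the TCPOBOP columns, and no call changed its sign by the quotient. The remaining large falls with PCN were Cyp2b9 (7.69-fold), Clec2h (6.54-fold) and Apol7a (6.03-fold) in the authors' deposited table. The PCN libraries are labelled unstranded, at odds with the kit named for them, and if the label holds, overlapping genes on opposite strands cannot be separated in them.

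**Figure D3:**
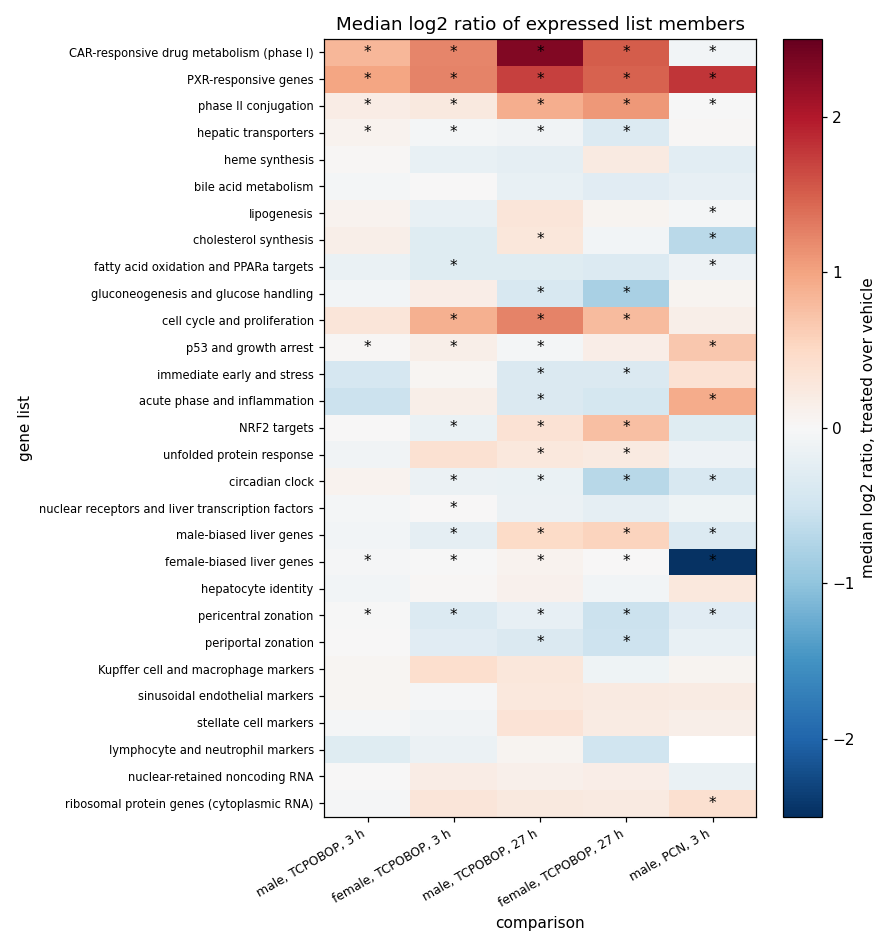
Median log2 ratio of the expressed members of each gene list with at least 5 expressed members (colour scale, red higher and blue lower after treatment) in the 5 comparisons. An asterisk marks lists whose share of calls passed adjusted p below 0.05 by Fisher's exact test, which does not look at direction. The PXR list was positive throughout, from 0.98 in 3 h males to 1.79 with PCN, and the CAR list stood at -0.07 with PCN.

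The median and the mean log2 ratio of a list that passed differed in sign for some lists whose members went both ways. These were pericentral genes at 3 h in both sexes and in 27 h males, transporters, NRF2 targets and clock genes in 3 h females, growth arrest genes in 27 h males, and female-biased genes in 3 h females and in both sexes at 27 h. With PCN they were the CAR list, at a median of -0.07 and a mean of 0.92, conjugating enzymes and lipogenic genes. With a minimum of 2-fold, transporters lost their call at 3 h in both sexes and NRF2 targets lost theirs in 3 h females and in both sexes at 27 h. Fatty acid oxidation, clock, liver transcription factor and pericentral genes also lost theirs in 3 h females. Cholesterol synthesis, glucose-handling, unfolded protein response and periportal genes did so in 27 h males, and lipogenic, male-biased and ribosomal protein genes with PCN.

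Markers of other liver cell types were examined as lists. Kupffer cell, stellate cell, lymphocyte and neutrophil, and sinusoidal endothelial lists passed in none of the comparisons in which they were tested by Fisher's exact test. Their medians were not at 0 throughout. In 27 h males the Kupffer cell, stellate cell and sinusoidal endothelial lists stood at 0.28, 0.34 and 0.26, each above 99% of random lists, and in 3 h females the Kupffer cell list stood at 0.42, also above 99%. The lymphocyte and neutrophil list stood at -0.30 in 3 h males and at -0.49 in 27 h females, below 99% of random lists. Sinusoidal endothelial genes had 5 raised of 14 in 27 h males (Pecam1, Kdr, Tek, Cdh5 and Oit3) with adjusted p = 0.103 for the list. Hepatocyte identity genes, heme synthesis, bile acid metabolism and nuclear-retained noncoding RNA passed in no comparison either. The cholangiocyte, erythroid and sex-chromosome lists had fewer than 5 expressed members and were not tested. Among the members of these, Alas2 rose 1.92-fold in 27 h females by the authors' deposited table.

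Responses of the sexes and times were compared by their calls. At 3 h, 93 genes were raised in both sexes where 3.23 were expected, 7 were lowered in both where 0.913 were expected, and 2 had opposite directions. At 27 h, 438 genes were raised in both sexes (56.9 expected), 342 were lowered in both (45.4 expected) and 7 had opposite directions. Spearman's rho of the log2 ratios between the sexes, across genes that are not independent replicates, was 0.23 at 3 h and 0.70 at 27 h. Between 3 h and 27 h, males shared 102 raised (10.5 expected) and 33 lowered genes (3.60 expected) with none opposite, and females shared 153 raised (17.9 expected) and 68 lowered genes (10.4 expected) with 12 opposite. Genes raised in all 4 TCPOBOP comparisons numbered 80, and 48 of them were also raised by PCN, among them Cyp2b10, Cyp2c55, Cyp3a11, Por, Alas1, Gadd45a and Gadd45b. Genes lowered in all 5 comparisons were Ang, Rnase4 and Rdh16, named after their values were seen, and the first pair overlap on the genome. Against the other vehicle group of the same sex, Ang and Rnase4 did not hold in 3 h females, nor Rdh16 in 27 h females.

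TCPOBOP and PCN differ in structure and in dose. Their libraries form separate sets that also differ in labelled library type, pools per group and estimated depth. The male 3 h vehicle groups of these sets were at least 2-fold apart in 423 genes. Compound and set cannot be told apart here, although each ratio is against its own vehicle. The difference between the compounds was not tested, since the authors' deposited table has no value per pool. In males at 3 h, 71 genes rose with both (15.3 expected), 12 fell with both (4.33 expected) and 19 had opposite directions, with a Spearman's rho across genes of 0.17. Nnmt fell 2.87-fold with TCPOBOP and rose 13.7-fold with PCN, and Gadd45g fell 2.07-fold and rose 2.52-fold, in the authors' deposited table. Cyp2b10 rose 112-fold with TCPOBOP and 31.1-fold with PCN, and Gadd45b rose 11.6-fold and 54.1-fold, in the authors' deposited table. In 3 h females, TCPOBOP shared 154 raised genes (28.4 expected) and 106 lowered genes (16.03 expected) with PCN in males, with 11 opposite and a rho of 0.48, and the difference from 3 h males was not tested. Male TCPOBOP calls at 27 h and PCN calls at 3 h, which differ in time as well, shared 190 raised (88.5 expected) and 160 lowered genes (68.5 expected) with 174 opposite. No expected number was computed for opposite calls, so these 174, like the 19 and 11 above, cannot be read as few or many. Of the genes called in both, 66.8% moved the same way, and 76.8% did so at a minimum of 2-fold.

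Sex bias in vehicle liver was described without a test. At 3 h, 156 genes were at least 2-fold higher in females and 180 in males, and at 27 h these numbers were 299 and 542. Between 3 h and 27 h the female vehicle pools were at least 2-fold apart in 1445 genes and the male ones in 284. The larger numbers at 27 h thus cannot be read as a wider sex bias. Both times together gave 69 female-biased and 86 male-biased genes. The largest female bias was in Sult3a1, at 113.9 FPKM in female and 0.0453 FPKM in male vehicle liver at 3 h in the authors' deposited table, followed by Xist, Cyp2b13, Cyp3a16 and Sult2a1. The largest male bias was in the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d and in Cyp4a12a, which stood at 24.6 FPKM in males and 0.0518 FPKM in females at 27 h in the authors' deposited table.

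TCPOBOP at 27 h in females raised 200 male-biased genes and lowered 5, and lowered 111 female-biased genes and raised 22 (p = 1.86e-59, Fisher's exact test on gene counts). The same vehicle pools entered both the bias and the response, which pushes both that way. With bias taken from the 3 h vehicle pools, which share no library with the response, 41 male-biased genes rose and 17 fell, and 31 female-biased genes fell and 19 rose (p = 0.000916, Fisher's exact test). The response itself was still against the female 27 h vehicle pools. These differed from the female 3 h vehicle pools by at least 2-fold in 1445 genes. How many of these rises and falls held against the 3 h vehicle pools was not counted. In 27 h males, 139 male-biased genes rose and 33 fell and 47 female-biased genes moved each way (p = 3.16e-07, Fisher's exact test). With bias from the 3 h vehicle pools, 49 male-biased genes rose and 17 fell and 20 female-biased genes rose and 25 fell (p = 0.00257, Fisher's exact test), and with bias required at both times the difference was not past the threshold (p = 0.298, Fisher's exact test). In 3 h females, 25 female-biased genes rose and 6 fell, and 14 male-biased genes rose and 13 fell (p = 0.0264, Fisher's exact test). In 3 h males, 15 female-biased genes rose and 5 fell and 10 male-biased genes rose and 1 fell (p = 0.383, Fisher's exact test). With PCN the result turned with the vehicle pools that defined the bias. By the 3 h pools 39 female-biased genes rose and 24 fell while 20 male-biased genes rose and 54 fell, and by the 27 h pools 34 and 70 did so against 70 and 51. With bias required at both times, 10 female-biased genes rose and 15 fell and 11 male-biased genes rose and 21 fell (p = 0.784, Fisher's exact test).

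**Figure D4:**
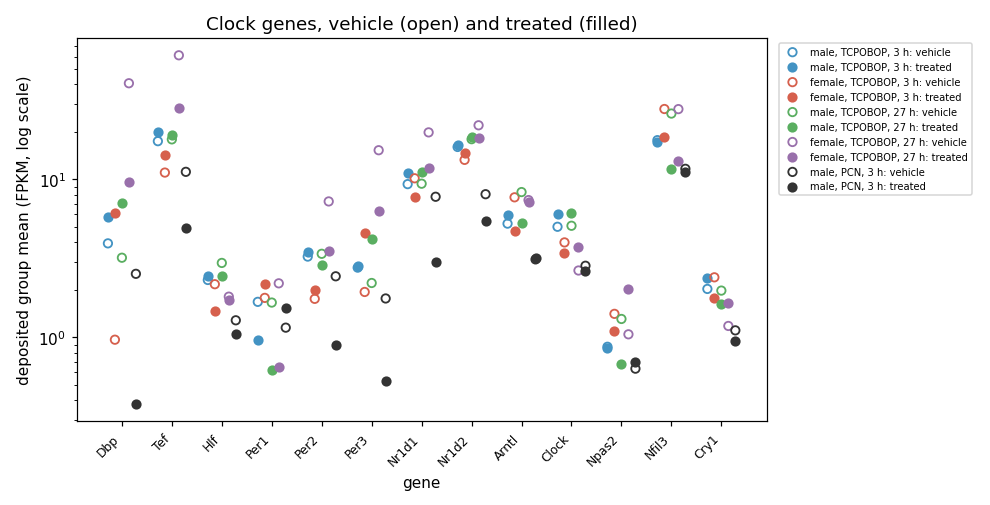
Mean FPKM (log axis) of 13 clock genes in vehicle pools (open circles) and treated pools (filled circles) of the 5 comparisons, from the authors' deposited table. The female 27 h vehicle pools stood apart in Dbp at 40.6 FPKM and in Per3 at 15.3 FPKM. The other vehicle groups lay between 0.966 and 3.94 FPKM in Dbp and between 1.76 and 2.76 FPKM in Per3.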

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

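The genes below were called in opposite directions in the 2 sexes or at the 2 times of TCPOBOP treatment. The difference itself was not tested, because the authors' deposited table has no value per pool. Each difference is the later-named log2 ratio minus the earlier one, and the larger of the 2 adjusted p-values stands beside it. Chosen only after the result was seen were the tests of daily phase in the female vehicle pools, of displacement by TCPOBOP, and of scaling in the PCN set, and the comparison with the vehicle group of the other time.

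At 3 h, the nicotinamide-methylating enzyme gene Nnmt had a log2 ratio of -1.52 in males and 1.14 in females, a difference of 2.66 (larger adjusted p = 0.0296) by the authors' deposited table. The noncoding C730036E19Rik stood at 1.81 in males and -1.08 in females, a difference of -2.89 (1.03e-07), in the authors' deposited table. Its female fall did not hold against the female 27 h vehicle pools.

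At 27 h, the clock output gene Dbp rose 2.29-fold in males and had a log2 ratio of -2.03 in females, a log2 difference of -3.22 (larger adjusted p = 3.15e-06), in the authors' deposited table. Another clock gene, Per3, stood at log2 ratios of 0.97 and -1.22, a difference of -2.19 (2.63e-05), and Npas2, of the opposite daily phase, at -0.88 and 1.03, a difference of 1.91 (0.0142), in the authors' deposited table. Cwc22, a splicing factor gene, stood at -0.91 and 1.66, a difference of 2.57 (0.0283), and Slc41a2 at -0.81 and 0.78, a difference of 1.59 (0.0103), in the authors' deposited table. The noncoding 4930404H11Rik stood at 1.10 and -2.87, a difference of -3.96 (0.00223), and Rmrp at 1.89 and -1.54, a difference of -3.43 (0.0118), in the authors' deposited table. Against the 3 h vehicle pools of the same sex, the female directions of Dbp, Per3 and Slc41a2 and the male direction of Cwc22 did not hold.

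In females, 5 genes were raised at 3 h and lowered at 27 h. Dbp went from 2.72 to -2.03, a difference of -4.74 (larger adjusted p = 0.0163), and Per3 from 1.30 to -1.22, a difference of -2.52 (0.00196), in the authors' deposited table. Nnmt went from 1.14 to -2.19, a difference of -3.33 (0.0296), Asap3 from 0.78 to -0.80, a difference of -1.58 (0.00698), and Cyp2a4 from 0.70 to -1.18, a difference of -1.88 (0.00222), in the authors' deposited table. For Dbp, Per3 and Asap3, neither direction held against the female vehicle pools of the other time.

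Another 7 genes were lowered at 3 h and raised at 27 h in females. The major urinary protein gene Mup3 went from -0.73 to 1.03, a difference of 1.76 (larger adjusted p = 0.00555), and the fatty acid binding protein gene Fabp2 from -1.02 to 1.25, a difference of 2.27 (0.0169), in the authors' deposited table. The receptor gene Fzd7 went from -0.81 to 0.77, a difference of 1.58 (0.0192), and the tight junction gene Cldn1 from -0.81 to 0.75, a difference of 1.56 (0.0253), in the authors' deposited table. Dntt went from -1.04 to 2.39, a difference of 3.42 (0.0133), Keg1 from -1.20 to 1.25, a difference of 2.45 (9.57e-05), and BC021614 from -2.27 to 2.10, a difference of 4.38 (0.0193), in the authors' deposited table. Neither direction of Mup3, Fabp2 and Cldn1 held against the female vehicle pools of the other time, nor did the 27 h rise of Fzd7.

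The clock genes Dbp, Per3 and Npas2 were called in opposite directions in the sexes at 27 h of TCPOBOP. Between the female 27 h and 3 h vehicle pools, the 9 genes that peak with Dbp differed from 5 genes of the opposite phase by a median log2 of 2.39 (exact permutation p = 0.0150), so that another daily phase in the female 27 h vehicle pools is a candidate explanation. All permutations in this paragraph exchanged genes, which are not independent, so their p-values do not measure the spread between pools. Dbp, Per3 and Npas2, whose opposite calls prompted the tests, were among the genes tested. A displacement by TCPOBOP from the 3 h vehicle phase stays open, since the female TCPOBOP pools of 27 h differed from the 3 h vehicle pools by 1.07 (exact permutation p = 0.0809), and the bound first set, a difference smaller than that of the vehicle pools, does not exclude one. Whether the female 27 h calls as a whole rest on these vehicle pools stays undecided, since 62.5% of them (60.4% of those expressed) had the same direction against the 3 h vehicle pools, against 44.2% of expressed genes that were not called, and the bounds of 60% and 90% were set without regard to the treated pools that both quotients share. A response of the clock to TCPOBOP that differs between the sexes stays open and was not tested, as the TCPOBOP pools differed from their own vehicle by 0.74 in males (exact permutation p = 0.145) and by -1.48 in females (exact permutation p = 0.0400), and the male vehicle pools of the 2 times by -0.53 (exact permutation p = 0.0400).

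Ribosomal protein genes rose with PCN. By quotients of mean FPKM the list stood 0.38 above all expressed genes, higher than 99.6% of matched lists. A scaling factor moves all genes of a library alike and leaves that place among genes unchanged. The comparison therefore restates the place of the list and decides nothing about the authors' scaling. A candidate explanation is more cytoplasmic RNA in the PCN nuclei, since 77 genes of the respiratory chain, also abundant as cytoplasmic mRNA, had a median log2 ratio of 0.26, with 14 raised and 0 lowered. Over all 8918 expressed genes the median of the authors' log2 ratios was 0.03, with 1150 raised and 839 lowered. A rise in transcription of both gene groups would look the same, and the medians of the ribosomal list in 3 of the TCPOBOP comparisons (0.29, 0.24 and 0.22) leave open whether the pattern belongs to PCN.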

How the results depend on the processing

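Chosen only after seeing the data were the vehicle group of the other time, the sign from mean FPKM, the background of 0.1 FPKM and sex bias at both times. Kept within 1.5 times were the counts of genes at 1 FPKM or more (185, 449, 1711, 1355 and 1989 for male and female 3 h, male and female 27 h and PCN) and, with a background of 0.1 FPKM, of gene lists (8, 15, 17, 18 and 18 against 7, 13, 17, 14 and 13). With the sign from mean FPKM no call changed sign, and of 70 log2 ratios of the genes fixed in advance, Ccnd1 with PCN, not a call, went from 0.13 to -0.06. A minimum of 2-fold, which removes calls by construction, left 107, 212, 644, 749 and 608 genes of 210, 507, 2046, 1536 and 2366, and turned the PCN majority from 53.4% to 47.7% raised, the cause of which was not tested. Of 7, 13, 17, 14 and 13 lists, 6, 7, 12, 13 and 10 kept their call with it (7, 7, 12, 14 and 12 passed), and the share of genes that male TCPOBOP at 27 h and PCN moved the same way went from 66.8% to 76.8%. An adjusted p of 0.01 left 950 genes in 27 h females and 151, 344, 1374 and 1588 in the others. Against the vehicle group of the other time, 960 genes in 27 h females had the same direction, and 189, 449 and 1752 in the other TCPOBOP comparisons; the cause was not tested.

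The sex-bias result is the percent raised among called male-biased genes minus that among female-biased genes. In 3 h males it reversed from 15.9 to -17.2 with bias from the other time (Fisher's exact p = 0.383 and 0.237, neither past the threshold). In 27 h males it went from 30.8 to 29.8 with bias from the other time (Fisher's exact p = 0.00257) and to 14.9 with bias at both times (Fisher's exact p = 0.298), where fewer genes qualify. In 27 h females it was 81.0, and 32.7 and 61.8 under those alternatives, and in 3 h females -28.8, and -27.5 and -56.5. The alternatives change the vehicle pools that define the bias and not those behind the response.

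No paired analysis was possible because the table gives group means. Alternatives planned for fits to values per library were not run: other normalizations (RLE, DESeq2), the removal of filters, leaving out pools, the replicate block and set tests (camera, fry). Another pseudocount was not run either. The table has 1 statistic per comparison, so no second one was compared. A gene of 1 kb at 1 read per pool lies at 0.0214 to 0.0525 FPKM, which limits folds from lower levels. In a shorter gene 1 read is worth more, so the minimum of 1 FPKM rests on fewer reads there.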

Other observations

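Gene families defined by a shared symbol stem were tested for calls in 1 direction, in 1438 Fisher's exact tests with adjusted p-values, and these tests, and that of neighbours with raised ones kept, were chosen only after the result was seen. The major urinary protein genes, secreted pheromone carriers, were raised by TCPOBOP at 27 h in 11 of 14 expressed members in males (adjusted p = 1.70e-07) and in 10 of 14 in females (adjusted p = 4.13e-07). Mup1 rose 7.09-fold in females and 1.85-fold in males by the authors' deposited table. Of these calls, 2 of the 11 in males and 7 of the 10 in females had the same direction against the 3 h vehicle pools of the same sex, and reads of these near-identical genes cannot be separated. Sulfotransferase genes were raised in 7 of 10 members in 3 h females (adjusted p = 2.41e-07), among them Sult1d1 (2.70-fold) and Sult2a5 (2.62-fold) in the authors' deposited table, and 6 of the 7 kept their direction against the 27 h vehicle pools, Sult5a1 being the exception. The replication licensing family Mcm had 5 of 8 raised at 27 h in females (adjusted p = 0.00736) and in males (adjusted p = 0.0152), and all 5 in each sex kept their direction against the 3 h vehicle pools. Tmed genes, which encode cargo carriers of the secretory pathway, had 5 of 9 raised in 27 h males (adjusted p = 0.0261), of which 4 kept their direction. Retinol dehydrogenase genes were lowered at 3 h in 3 of 9 members in females (adjusted p = 0.0261) and in 2 of 9 in males (adjusted p = 0.0407), with Rdh16 down 1.88-fold and 2.11-fold in the authors' deposited table.

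With PCN, serine protease inhibitor genes of the Serpina family were raised in 12 of 20 members (adjusted p = 0.000167). Serpina3n rose 4.83-fold to 503 FPKM and Serpina3m rose 3.53-fold by the authors' deposited table. Host genes of small nucleolar RNA (Snhg) had 7 of 9 raised (adjusted p = 0.00217), with Snhg3 at 2.45-fold in the authors' deposited table. Ribosomal protein genes had 34 of 44 Rpl (adjusted p = 3.59e-19) and 22 of 36 Rps members raised (adjusted p = 5.04e-09). Carboxylesterase genes had 6 of 12 lowered (adjusted p = 0.0229), with Ces3a down 3.20-fold in the authors' deposited table, although Ces1c, Ces1d and Ces2a rose with PCN. TCPOBOP at 27 h raised 6 of 12 in females (adjusted p = 0.00736) and 6 of 12 in males (adjusted p = 0.0164). Hydroxysteroid dehydrogenase genes had 6 of 13 lowered with PCN (adjusted p = 0.0314), with Hsd3b2 down 3.09-fold in the authors' deposited table.

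Vehicle groups differed from each other by amounts that the treatment comparisons do not use. The SD of the log2 quotient of mean FPKM across expressed genes was 0.416 between the male 3 h and 27 h groups, 0.722 between the female 3 h and 27 h groups, 0.551 between the sexes at 3 h and 0.683 between the sexes at 27 h. Between the male 3 h vehicle groups of the TCPOBOP and PCN sets it was 0.711, with 423 genes at least 2-fold apart. These sets differ in their vehicle pools and in the library type given by the labels.

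A hypothesis was that transcription runs past the end of strongly raised genes into the next gene. Downstream neighbours within 50 kb on the same strand would then exceed upstream ones. At 27 h in males, 16 downstream neighbours of 72 genes raised at least 4-fold had a median log2 ratio of -0.08 and 9 upstream ones had 0.29, a difference of -0.37 (permutation p = 0.0875, 95% bootstrap interval -0.91 to -0.06). In females, 15 downstream neighbours of 77 such genes stood at 0.17 and 11 upstream ones at 0.62, a difference of -0.45 (permutation p = 0.139, 95% bootstrap interval -0.80 to 0.05). These values decide nothing, because neighbours themselves raised at least 4-fold had been left out. With them kept, 2 more neighbours entered in males, neither of which changed the difference of -0.37, and 3 in females, where the difference was -0.45 (permutation p = 0.1005, 95% bootstrap interval -0.999 to -0.07). The predicted excess of downstream over upstream neighbours was not seen in either sex, and neither interval of this second test reaches the bound of 0.1. The upstream neighbours stood at 0.29 in males and 0.62 in females and were no neutral reference. A rise around the raised genes on both sides would hide an excess, so the hypothesis is not excluded. The intervals were added after the differences had been seen.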
